A study of Arabidopsis thaliana with 12 samples.

How the data were processed

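Gene expression was measured in roots of 7-day-old Arabidopsis thaliana seedlings with Affymetrix ATH1 arrays, 1 array per RNA sample. Per the labels, seed was kept for 2 days at 4 °C, and seedlings grew at 24 °C with 16 h of light and 8 h of dark on medium of 0.5 strength with 1% agar. The 12 arrays fell into 4 groups of 3 by their titles. The groups were wild-type Col-0, a line in the Col-0 background carrying 35S:Ara1YFP (ara1OX), wild-type Col-3, and a mutant of both ARABIDILLO genes in the Col-3 background (ara1/2mut). The labels number the replicates but do not say whether they came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

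The deposited values are intensities on a linear scale, computed with MAS5 per the submitters' processing notes. The MAS5 version and its target value are not given in the sources used here. In the deposited table every array had a trimmed mean signal of 100 after leaving out 2% of the values at each end, so each array had been scaled, and no other normalization was visible. Detection calls were not used here. Such scaling fixes the overall level of each array, so a change of all transcripts together would not be seen.

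The values were analysed as log2 signal without further normalization. Of 22810 probe sets, 64 Affymetrix controls were left out. Probe sets with a mean log2 signal at or above the 40th percentile (4.49, a signal of 22.4) were kept, which left 13648. All 12 arrays entered 1 linear model with a coefficient per group in limma 3.58.1 (R 4.3.3), with moderated variances following the trend with signal. There were 8 residual and 7.49 prior degrees of freedom. Tests were two-sided, and a Benjamini-Hochberg adjusted p under 0.05 counted as changed. The contrasts were ara1OX against Col-0, ara1/2mut against Col-3, Col-3 against Col-0, and the difference between the first and the second. Opposite movement was counted at an unadjusted p under 0.01 in both lines. The number of arrays limits the precision.

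The platform's gene table listed 14016 probe sets, 13513 with 1 gene and 503 with several. The other 8730 non-control probe sets are unnamed here. Through the gene table of assembly TAIR10.1, used only for names and for gene order, 13436 probe sets were matched to 13286 genes. Neither ARABIDILLO-1 nor ARABIDILLO-2 had a named probe set, so the levels of the targeted genes, planned as the first check of the labels, are not analysed here. Before the data were examined, 24 gene lists holding 366 genes were fixed. Of these genes 37 had a named probe set and 25 passed the filter, and 1 list kept at least 5 genes. A further gene was dropped because its symbol was contradicted by the table. Lists were tested with camera at a preset correlation of 0.01, and again with the correlation estimated, over 7252 genes with 1 probe set each.

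Because so few listed genes were named, 38 families were added after seeing the data, built from gene symbols, from names, from the plastid genome, and 1 hand-made set of 9 extensins. The extensins were picked because several of them led the ranking of single genes. A separate set of 9 root hair genes other than extensins, chosen from general knowledge, was written before the values of 7 of them had been looked at.

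Named genes followed a rule written before the data were examined. It took all changed named genes up to 10 per direction, filled up to 8 (5 for Col-3 against Col-0) with the genes of smallest p whose groups did not overlap, and up to 4 members of each list (3 for Col-3 against Col-0). The unnamed probe sets that passed, the extensins and the other root hair genes fall outside that rule and were chosen after their values were seen, except for the 7 genes mentioned above.

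The procedure was tested on simulated data with the spread of the real arrays and 13648 probe sets. For ara1OX against Col-0 it recovered 54% of 100 changes of log2 1 and 94% of 100 changes of log2 2, with 8 false calls. For ara1/2mut against Col-3 it recovered 56% and 96%, with 11 false calls. With no change simulated it made 0 calls in both. A shift of 0.5 in a list of 9 genes was found in 100 of 100 lists, and 4 of 100 unshifted lists were called. The simulated genes varied independently of each other. The simulation therefore does not show how often lists of correlated genes are called falsely. Changes of both sizes were planted in the same simulated data, and with fewer true changes the adjusted threshold is stricter. The shares recovered may therefore be too high for comparisons with few calls. Each simulated probe set also had the same spread in all groups. In the real arrays the residual SD was 0.41, 0.29 and 0.39 in ara1OX against 0.28, 0.24 and 0.25 in Col-0.

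The alternatives were quantile normalization, median centring, no filter, a filter at the 60th percentile, a pseudocount of 16, no variance trend, array weights, a fit of only the groups compared, the replicate number as a block, an estimated correlation in camera, and leaving out each array in turn. Leaving out ara1OX arrays 1 and 3 together and adding the spike-in level as a covariate were chosen after seeing the data, as was a ratio of 3' to 5' probe sets as a covariate, which was run for the mean extensin level only. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.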

Results

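ARABIDILLO-1 and ARABIDILLO-2 encode F-box proteins with Armadillo repeats that promote lateral root development. The series asked which genes depend on them. It compared roots that overexpress an ARABIDILLO-1 fusion to yellow fluorescent protein (ara1OX) with their Col-0 wild type, and roots of a double mutant (ara1/2mut) with their Col-3 wild type, with 3 arrays in each of 4 groups. For each array, the correlations across probe sets with the other arrays of its group were averaged. This mean r was 0.959 ± 0.00402 in Col-0 (SD of the array means, n = 3), 0.922 ± 0.0119 in ara1OX, 0.959 ± 0.00590 in Col-3 and 0.937 ± 0.00993 in ara1/2mut. The array means of a group share correlations, so this SD is smaller than the spread of r between arrays. The spiked-in hybridization controls of ara1OX replicate 3 were 5.15-fold those of the median array. Their mean log2 signal was 8.54 ± 0.32 in Col-0, 9.10 ± 1.47 in ara1OX, 8.11 ± 0.35 in Col-3 and 8.99 ± 0.49 in ara1/2mut.

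In ara1OX roots 3 probe sets rose against Col-0, and none fell. All 3 are unnamed here. Probe set 266815_at rose most, from a signal of 52.9 ± 7.58 in Col-0 to 402 ± 112 in ara1OX (SD, n = 3). This was a 7.45-fold difference, with a log2 fold change of 2.90 (SE 0.36). Probe set 262454_at rose 2.51-fold, from 104 ± 11.9 to 261 ± 24.5. Probe set 265032_at rose 2.42-fold, from 135 ± 14.2 to 324 ± 16.9. Each of these 3 had a limma adjusted p of 0.00287, and in each the lowest ara1OX array lay above the highest Col-0 array. At an unadjusted limma p under 0.05 there were 877 probe sets, 319 higher and 558 lower, where 682 would be expected by chance.

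**Figure D1:**
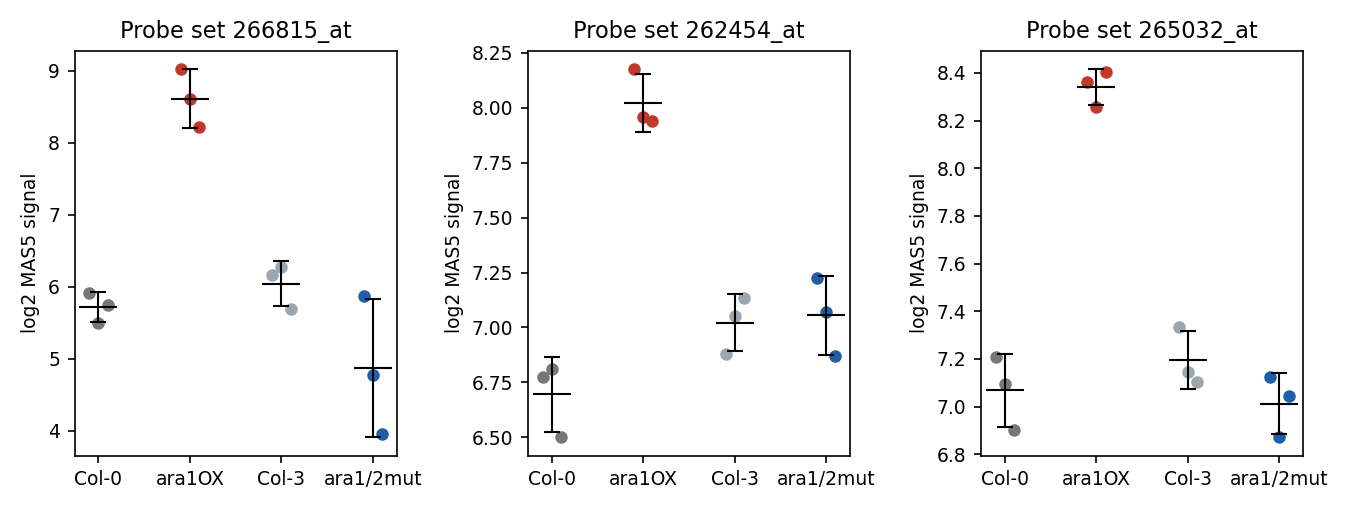
Log2 MAS5 signal of probe sets 266815_at, 262454_at and 265032_at in each array (points) of the 4 groups, with the mean (horizontal line) and SD (bars, n = 3). The axes do not start at 0. In each panel all 3 ara1OX arrays lie above the other 9.

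No named gene passed the test in ara1OX. The closest was AT2G41730, with a log2 fold change of 1.07 (SE 0.18) and an adjusted p of 0.0616. Its probe set carries the suffix x, which marks probes shared with other transcripts. Among the settings in which it passed were no filter, the filter at the 60th percentile, a pseudocount of 16, array weights and leaving out ara1OX replicate 2. Among the other genes with higher values, AT5G07570 and AT4G34320 had log2 fold changes of 1.64 and 1.65, AT5G38610 had 1.27, AT1G73340 had 1.07, AT4G04460 had 0.97, AT5G16010 had 0.84 and the lipocalin gene TIL had 0.81. Their adjusted p-values ran up to 0.204. Among the genes with lower values were UGT72E1 and UGT72E3, which encode glycosyltransferases, with log2 fold changes of -1.01 (adjusted p 0.109) and -1.42 (adjusted p 0.170). The cytochrome P450 gene CYP71B23 had -0.93, the glutaredoxin gene GRXC1 had -0.80 and IYO had -2.12. AT4G07820, AT5G37450 and AT1G74240 had -1.16, -2.28 and -2.34. These 6 genes had adjusted p-values from 0.140 to 0.204. In ara1OX the mean signals of AT5G37450, AT1G74240, IYO and UGT72E3 were 17.0 ± 14.4, 9.94 ± 7.40, 14.7 ± 13.1 and 23.1 ± 10.6 (SD, n = 3). Such signals lie near or below the filter signal of 22.4, so the sizes of these log2 fold changes are uncertain. The signal of AT4G34320 in Col-0, 22.6 ± 1.38, also lay near it. With array weights 15 probe sets passed, UGT72E1, CYP71B23, AT4G07820 and AT1G74240 among them, and without ara1OX replicate 2 there were 14, UGT72E3, IYO and AT5G37450 among them. Replicate 2 had the highest array weight in ara1OX, 2.17 against 0.51 for replicate 1 and 0.50 for replicate 3. In the fit of only the arrays compared 5 passed, with AT5G07570 and AT4G07820 among them. With the replicate number as a block 17 passed, among them AT2G41730, AT5G07570, AT5G37450, AT4G07820, UGT72E1, AT1G73340 and AT5G16010.

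Of the 25 listed genes measured in ara1OX, 0 passed, over all probe sets and also adjusted over the list alone, and 2 had an unadjusted limma p under 0.05. The lateral root transcription factor genes LBD16, LBD29 and PUCHI had log2 fold changes of 0.09 (SE 0.21), 0.35 (SE 0.45) and 0.44 (SE 0.43). The auxin-responsive genes GH3.3 and WES1 had 0.40 (SE 0.36) and 0.08 (SE 0.15). The gibberellin receptor gene GID1A had -0.71 (SE 0.32), and the root hair expansin genes EXPA7 and EXPA18 had 0.37 (SE 0.17) and 0.25 (SE 0.17). The shoot markers RCA and LHCB4.1 had -0.02 (SE 0.26) and 0.01 (SE 0.32). SKP2A, LTI30, COR47, PRL, XTH18, XTH19, XTH20, GI, RTE1, GID1B, BHLH101, JKD and STZ lay between -0.69 and 0.13. The 5 measured genes of cell wall expansion had a median of -0.29 (camera adjusted p 0.440), with EXPA4 at -0.34 and EXPA15 at -0.45. With an estimated correlation the adjusted p was 0.664.

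In ara1/2mut roots 0 probe sets passed against Col-3 in limma, and the smallest adjusted p was 0.759. At an unadjusted p under 0.05 there were 486 probe sets, 243 higher and 243 lower, where 682 would be expected by chance. The genes with the smallest p among those with higher values were mostly wall proteins of the extensin family. AT5G06630 had a log2 difference of 1.34 (SE 0.29), AT3G28550 had 1.23 (SE 0.27), AT4G08410 had 1.02 (SE 0.28), AT3G54580 had 0.97 (SE 0.28) and the hydroxyproline-rich glycoprotein gene HRGP1 had 0.85 (SE 0.23). AT2G39260, AT2G31370 and the RNA helicase gene PRH75 had 0.91, 0.63 and 0.57. Among lower values were the carboxypeptidase-like gene scpl20 at -0.93, the asparaginase gene ASPGB1 at -1.07 and the plantacyanin gene ARPN at -0.91. AT2G01580, AT2G35750, AT5G22555, AT5G47550 and AT3G11250 had log2 differences from -0.66 to -0.94. The adjusted p-values of these 16 genes ran from 0.759 to 0.999. With array weights 4 probe sets passed, AT5G06630 among them, and without Col-3 replicate 3 the 1 that passed was AT3G28550.

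As a set, the 9 extensins were higher in ara1/2mut than in Col-3, with a median log2 difference of 0.97 and a camera adjusted p of 5.2e-13 over 38 families. With an estimated correlation the adjusted p was 0.160. The family was chosen after several of its members had been seen at the top of the ranking, so neither p is independent evidence. Of these probe sets 4 carry the suffix x. The 49 plastid-encoded genes had a median of 0.26 (adjusted p 2.1e-05), which became 0.07 (adjusted p 0.824) without ara1/2mut replicate 2. With an estimated correlation their adjusted p was 0.816. They had a median of -0.19 in ara1OX against Col-0 (adjusted p 0.0853) and of -0.12 in Col-3 against Col-0 (adjusted p 0.224).

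Of the 25 listed genes, 0 passed in ara1/2mut, over all probe sets and also adjusted over the list alone, and 0 had an unadjusted p under 0.05. LBD16, LBD29 and PUCHI had log2 differences of 0.20 (SE 0.21), 0.21 (SE 0.45) and -0.24 (SE 0.43). EXPA7 and EXPA18 had 0.13 and 0.24, GID1A had -0.05, and GH3.3 had 0.07. RCA and LHCB4.1 had 0.17 and 0.29. The other listed genes lay between BHLH101 and EXPA15, both at -0.42, and RTE1 at 0.56. The 5 genes of cell wall expansion had a median of -0.28 (camera adjusted p 0.369, and 0.614 with an estimated correlation).

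Between the wild types, Col-3 against Col-0, 0 probe sets passed in limma (smallest adjusted p 0.817). There were 694 at an unadjusted p under 0.05, 330 higher and 364 lower, where 682 would be expected by chance. The genes with the smallest p included CUTA at a log2 difference of 0.87, AT5G14330 at 1.38, AT2G27260 at 1.02, AT1G60610 at 0.67 and AT3G12040 at 0.66. Lower values were held by the extensin genes AT5G06630 (-1.14), AT1G23720 (-0.89) and HRGP1 (-0.85), and by the plastid genes ndhA (-1.03) and rps19 (-0.96). Each had an adjusted p of 0.817. The listed genes XTH18, which encodes a xyloglucan-modifying enzyme, and EXPA18 had -0.55 (SE 0.17) and -0.37 (SE 0.17), and the other listed genes lay between RTE1 at -0.48 and PUCHI at 0.59. Of the 25 listed genes 0 passed, over all probe sets and also adjusted over the list alone, and 2 had an unadjusted p under 0.05. The 5 genes of cell wall expansion had a median of -0.12 (camera adjusted p 0.0668, and 0.316 with an estimated correlation).

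The extensins were lower as a set in Col-3 than in Col-0, with a median log2 difference of -0.89 (camera adjusted p 1.1e-10, and adjusted p 0.273 with an estimated correlation). Because the family was chosen after the ranking had been seen, its p-values here and below are not independent evidence either. The mean log2 signal of the extensins was 8.35 ± 0.05 in Col-0 (SD, n = 3), 8.78 ± 0.48 in ara1OX, 7.54 ± 0.41 in Col-3 and 8.38 ± 0.10 in ara1/2mut. Both differences therefore rested on the same 3 Col-3 arrays, and ara1/2mut against Col-0, a contrast added after seeing the data, had a median of 0.01 (camera p 0.622). The signal ratio of 3' to 5' probe sets, a sign of RNA quality, was 0.839 ± 0.127 for GAPDH in Col-3, 1.04 ± 0.143 in Col-0 and 0.956 ± 0.187 in ara1/2mut. For actin it was 11.2 ± 0.448, 14.6 ± 2.14 and 15.1 ± 8.96 (25.2 in ara1/2mut replicate 1), and for ubiquitin 1.92 ± 0.194, 1.91 ± 0.0582 and 2.13 ± 0.145 in the same order. With the GAPDH ratio as a covariate, added after seeing the data, the mean extensin difference of -0.81 (SE 0.26, p 0.0145) between Col-3 and Col-0 became -0.74 (SE 0.33, p 0.0595), and that of 0.84 (SE 0.26, p 0.0119) between ara1/2mut and Col-3 became 0.80 (SE 0.29, p 0.0292). In ara1OX against Col-0 the family had a median of 0.52 (adjusted p 0.000559, and adjusted p 0.716 with an estimated correlation), which became 0.30 (adjusted p 0.179) without ara1OX replicate 3, the array with the high spike-in signal.

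**Figure D2:**
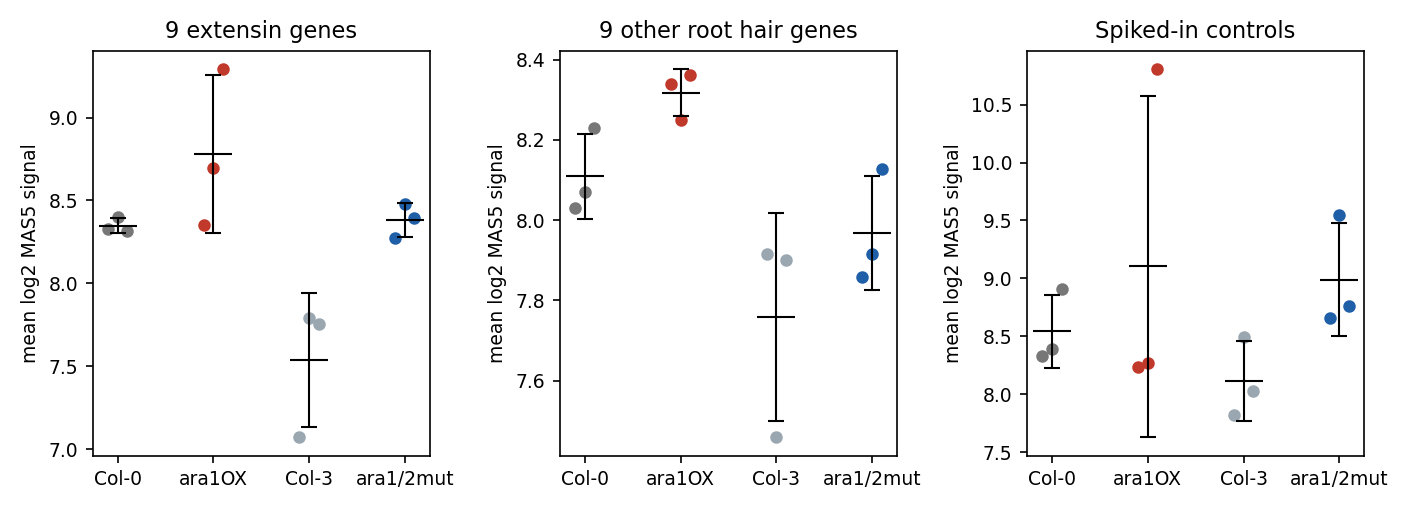
Mean log2 MAS5 signal per array (points) of 9 extensin genes, of 9 other root hair genes and of the spiked-in controls, with the group mean (horizontal line) and SD (bars, n = 3). The axes do not start at 0. The extensin mean was 7.54 in Col-3 and between 8.35 and 8.78 in the other groups, and the ara1OX spike-in mean had an SD of 1.47.

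The change in ara1OX differed from that in ara1/2mut for 2 probe sets in limma, with 724 at an unadjusted p under 0.05. For 266815_at the difference was 4.07 on the log2 scale (SE 0.51, adjusted p 0.00926), and its signal in ara1/2mut was 33.8 ± 22.1 against 67.1 ± 13.6 in Col-3 (SD, n = 3). Its log2 difference in the mutant alone was -1.18 (SE 0.36, adjusted p 0.999). For 265032_at the difference was 1.45 (SE 0.21, adjusted p 0.0305). For 262454_at it was 1.29 (SE 0.23, adjusted p 0.184). In the mutant alone these probe sets had log2 differences of -0.18 (SE 0.15) and 0.03 (SE 0.16), so their differences between the lines came mostly from ara1OX. The call of 266815_at was lost without Col-0 replicate 2, Col-3 replicate 2 or ara1/2mut replicate 2, where 0 probe sets passed, and 0 passed without the variance trend. The call of 265032_at was kept only without ara1/2mut replicate 1 among the 12 fits that left out 1 array, and was lost with median centring. Among named genes AT2G41730, AT3G58550, AT5G19570 and AT5G38610 had differences of 1.24, 1.11, 1.45 and 1.67, and AT5G07570 had a ratio of the 2 fold changes of 4.61. GRXC1, AT1G60770, CYP71B23, AT5G50310 and AT2G43800 had -1.27, -1.38, -1.07, -1.35 and -1.32. None of these 10 passed, with adjusted p-values from 0.365 to 0.735.

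The design also asks which genes moved in opposite directions in the 2 lines. At an unadjusted p under 0.01 in both comparisons, 2 probe sets did so and 0 moved the same way. Both were higher in ara1OX and lower in ara1/2mut, where 0.226 would be expected of independent lists. In the other opposite direction, lower in ara1OX and higher in ara1/2mut, there were 0, where 0.485 would be expected. The 2 probe sets were 266815_at and that of AT5G19570, which had a log2 fold change of 0.69 (SE 0.23) in ara1OX and -0.76 (SE 0.23) in ara1/2mut and did not pass in either. Across the 13648 probe sets, which are not independent replicates, the log2 fold changes of the 2 comparisons had a Pearson r of -0.04 and a Spearman rho of -0.05.

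**Figure D3:**
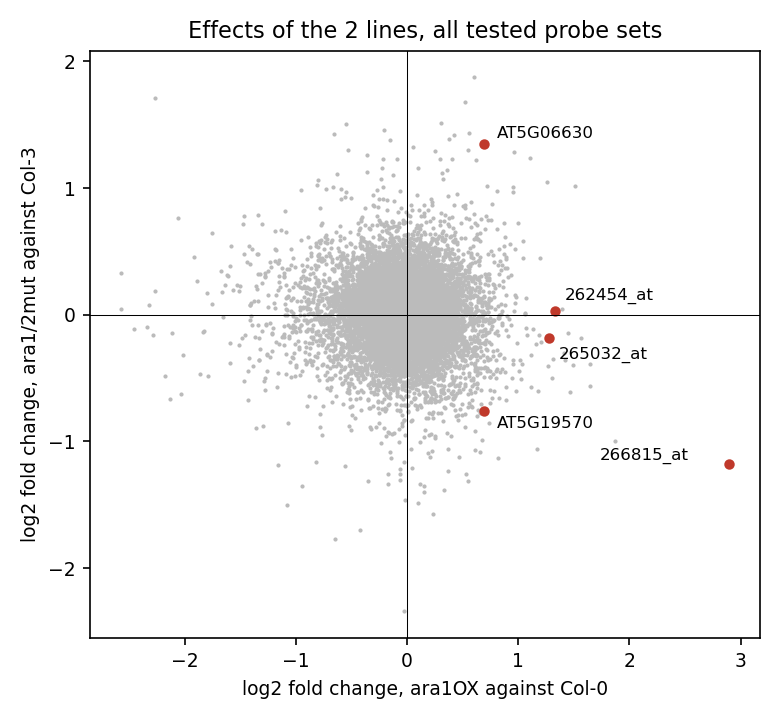
Log2 fold change of every tested probe set in ara1OX against Col-0 (horizontal axis) and in ara1/2mut against Col-3 (vertical axis), with 5 probe sets or genes marked in red. Probe set 266815_at lies at 2.90 and -1.18, and the cloud has an r of -0.04.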

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

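The splits, the spike-in covariate, the root hair tests with their fits without 1 array, and the bounds of every test weighed in this part were chosen after the results they bear on had been seen, while the contrast between the lines and the fits without 1 array for the called probe sets were planned. Probe sets 266815_at and 265032_at stood out because their change differed between ara1OX and ara1/2mut, by 4.07 and 1.45 on the log2 scale. Most of the difference for 265032_at came from ara1OX, since it had -0.18 (SE 0.15) in ara1/2mut against Col-3. Of 100 drawn splits of the arrays, 3 gave 2 or more probe sets whose change differed, the real one included, a share under 0.05. The highest other split gave 4, more than the real one, and the splits were chosen after the result had been seen. Chance is therefore not excluded.

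Leaving out any 1 of the 6 arrays moved the log2 fold change of none of the 3 probe sets that rose in ara1OX by more than 0.2045, and all 3 calls were kept in these 6 fits, which argues against a single array as the source. With the spike-in level as a covariate 3 of 3 calls were kept, which argues against hybridization level as the whole cause. The 6 arrays allow 10 splits, too few for a share under 0.05. The real split, 1 of the 10, gave 3 probe sets and the highest other gave 0. An effect of the ARABIDILLO-1 transgene, including its own transcript, stays open and was not tested, since none of the 3 probe sets is named here.

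The low extensin level of the Col-3 arrays was weighed second. With the spike-in level as a covariate its median went from -0.89 to -0.78 in Col-3 against Col-0 and from 0.97 to 0.60 in ara1/2mut against Col-3. This argues against hybridization level as the whole cause only if the spike-in level acts alike in all groups. The mean difference went from -0.81 to -0.68 (SE 0.18) and from 0.84 to 0.57 (SE 0.19), with a slope of 0.30 (SE 0.09) on the spike-in level. Part of each difference therefore went with the spike-in level. The 5 extensin probe sets without the suffix x had a median of 0.97 in ara1/2mut against Col-3, with 4 of 5 above 0 and a mean of 0.75 (SE 0.23 between arrays). This met the bound set for it. A form of the bound that asked for all 5 above 0, dropped after these values were seen, would not have been met. Of the 5, AT3G28550 (1.23) and AT3G54580 (0.97) were among the top-ranked genes for which the family was picked. The others were AT2G43150 at 1.07 (SE 0.44), AT1G26250 at 0.63 (SE 0.39) and AT1G26240 at -0.16 (SE 0.57). Because of that choice, these values cannot decide whether the probe sets with shared probes alone shifted. In Col-3 against Col-0 5 of 5 lay below 0, with a median of -0.57 and a mean of -0.68 (SE 0.26), which missed the same bound only through a spread term added after these values were seen, so there shared probes cannot be told apart from a change of the family, given the spread between 3 arrays. Lower activity of root hair genes in the Col-3 samples cannot be told apart from a change of the extensins alone, since 9 root hair genes other than extensins were lower in Col-3 than in Col-0 (median -0.37, camera p 4.16e-06, and p 0.0158 with an estimated correlation) and higher in ara1/2mut than in Col-3 (median 0.24, p 0.000437, and p 0.0481), but without Col-3 replicate 2 these became -0.28 (p 0.00545, and p 0.0939) and 0.13 (p 0.0856, and p 0.270), and a first rule without such fits, made stricter after the values were seen, had counted both for it. The arrays of Col-3 also parted, as replicate 1 had the lowest mean log2 signal of the extensins (7.07) and the highest of the root hair genes (7.92), and replicate 2 the highest of the extensins (7.79) and the lowest of the root hair genes (7.46).

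The spiked-in hybridization controls, which enter no comparison, were above every wild-type array in 2 arrays. They stood at 5.15-fold the median array in ara1OX replicate 3 and at 2.16-fold in ara1/2mut replicate 2.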

How the results depend on the processing

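Leaving out ara1OX arrays 1 and 3 together and all covariates were chosen after seeing the data. The 3 probe sets that rose in ara1OX stayed called under every alternative run for them except when both of those arrays were left out. The count for ara1OX was 15 with array weights, 5 with only the arrays compared, and 1 without ara1OX arrays 1 and 3, where a single array was assumed to vary like the others, and ran from 3 to 14 on leaving out 1 array (14 without ara1OX replicate 2, 5 without ara1OX replicate 3). The count for ara1/2mut was 4 with array weights and ran from 0 to 1. That for Col-3 against Col-0 ran from 0 to 2. The number that differed between the lines was 1 with median centring, 0 without the variance trend, and 1 without ara1OX arrays 1 and 3, and ran from 0 to 2. Opposite movement gave 1 probe set with median centring, with the filter at the 60th percentile and without the trend, 9 with array weights, and ran from 0 to 5. For Col-3 against Col-0, 1 gene list was called without the filter, and 0 to 1 on leaving out 1 array. The plastid-encoded genes, at -0.19 in ara1OX and -0.12 in Col-3 against Col-0 and not called, changed direction with array weights, to 0.0202 and 0.0238. They were called lower in ara1OX without the filter (adjusted p 0.00213), with the filter at the 60th percentile (0.0130), with only the arrays compared (0.0306), with the spike-in covariate (0.0162) and on leaving out any of 3 arrays (0.000394 to 0.0110), and in Col-3 without the filter (0.0449) and on leaving out any of 3 arrays (0.000840 to 0.0121). With an estimated correlation and the filter of the report the adjusted p was 0.838 in ara1OX and 0.681 in Col-3 against Col-0. In Col-3 against Col-0 they ran from -0.27 to 0.12 on leaving out 1 array, above 0 without Col-0 replicate 1. GID1A turned to 0.0523 without ara1OX arrays 1 and 3. Probe set 262454_at in ara1/2mut turned to -0.0390 without Col-3 replicate 1 and ran from -0.0528, without ara1/2mut replicate 1, to 0.13. The cause of these changes was not tested, except that fewer arrays weaken a test. The levels of the targeted genes and their alternatives were not run, since neither gene has a named probe set. With the actin or ubiquitin ratio as a covariate the mean extensin difference was -0.93 or -0.81 in Col-3 against Col-0 and 0.93 or 0.68 in ara1/2mut against Col-3. Signal over background limits probe sets near the filter.

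Same-numbered arrays had deviations correlating at 0.14, 0.03 and 0.12 for ara1OX and Col-0, at 0.18, 0.10 and 0.26 for ara1/2mut and Col-3, and at 0.00, -0.08 and 0.02 for the wild types. These values do not settle whether arrays of the same number were handled together. As a hint from the data, correlations were averaged by number over the arrays of the other groups, and for 8 of 12 arrays their own number had the highest mean. With the replicate number as a block, ara1OX gave 17 calls, 9 higher and 8 lower, which included the 3, AT2G41730, AT5G07570, UGT72E1 and other named genes, opposite movement gave 7, and the other counts did not move by more than 1.5 times.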

Other observations

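Of the tests in this part, those on the root hair genes and the splits were chosen after their results had been seen, and those on the neighbourhood of the mutated loci before. Among the single root hair genes other than extensins, none passed in any comparison. In Col-3 against Col-0 the peroxidase gene AT3G49960 had a log2 difference of -0.66 (SE 0.19), AT1G34510 had -0.52 (SE 0.18) and AT5G04960 had -0.38 (SE 0.14), and all 9 genes of the set lay below 0. In ara1OX against Col-0 the set had a median of 0.26, with 7 of 9 genes above 0 (camera p 0.000295, and p 0.0432 with an estimated correlation, which rose to 0.117 without Col-0 replicate 2). The 7 genes whose values had not been looked at when they were listed had a median of -0.38 in Col-3 against Col-0 (p 1.02e-05, and p 0.00678 with an estimated correlation), 0.25 in ara1/2mut against Col-3 (p 0.00137, and p 0.0304) and 0.26 in ara1OX against Col-0 (p 0.00382, and p 0.0450). The second of these rested on Col-3 replicate 2, without which it was 0.13 (p 0.0860, and p 0.189), and without ara1/2mut replicate 3 it was 0.16 (p 0.0443, and p 0.133). Without Col-3 replicate 2 the first was -0.28 (p 0.00380, and p 0.0440), and the third reached an estimated-correlation p of 0.131 without Col-0 replicate 2. The first 2 of these share the Col-3 arrays. These p-values were not adjusted over the comparisons.

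A mutant line can carry linked differences around the mutated loci. The mean absolute limma t of the 40 nearest measured genes in ara1/2mut against Col-3 was 0.67 around ARABIDILLO-1, at percentile 13.1 of 7008 windows of 40 genes, and 0.78 around ARABIDILLO-2, at percentile 49.9. Both lay below the 95th percentile set beforehand, so no regional shift was found. A change of 1 or a few genes would not move such a mean.

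With a real count of 0, every split of the arrays gives at least as many calls, so counting splits tests nothing for ara1/2mut against Col-3 or for Col-3 against Col-0. In both, 10 of 10 splits did so, and the highest other split gave 0 in the former and 1 in the latter.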
